A study of Ostrea lurida with 36 samples.

How the data were processed

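RNA sequencing was used to measure transcript levels in whole oysters. Each of 36 libraries came from the total RNA of 1 whole adult oyster, with all tissues included, and was made with a stranded kit (NEB Ultra Directional). Paired reads of 150 bp were sequenced with 12 libraries in each of 3 lanes. The deposited tables hold raw counts per contig (unit: counts), 1 table per library, with no scaling, for the contigs of the transcriptome that the authors assembled and deposited as sequences. DESeq2 and R 3.3.2 are named per the submitters' processing notes, with no model formula. The aligner, the counting tool and the assembler are not given in the sources used here.

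The assembly held 51574 contigs and 85799458 bp, with lengths of 200 to 33424 bp, a median length of 1147 bp, an N50 of 2604 bp and a GC content of 40.02%. Of these contigs, 12670 had counts in every library and 129 had none in any. Contigs carry running numbers and no gene names, and annotation was not used here. Families were therefore assigned from the longest open reading frame of each contig (6 frames, at least 50 residues, found in 49378 contigs), by an exact match to a protein signature or, for ribosomal proteins, core histones and mitochondrial genes, by a conserved peptide with at most 4 substitutions. The same search on reversed proteins gave the number of chance hits. Contigs are named by family and length of the open reading frame, such as a 650-residue HSP70-family contig, since a signature gives a family and not an orthologue. Reads shared between contigs of near-identical paralogs cannot be seen in the counts, so that the split of a family's reads among its contigs is uncertain.

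Total counts ranged from 0.321 to 16.131 M per library, with a median of 7.166 M. A floor of 3 counts, the upper limit that a count of 0 allows, corresponded to between 0.186 CPM in Loch Lomond control replicate 6 and 9.338 CPM in Loch Lomond low replicate 3. Reads without molecular identifiers are not independent molecules, so floors cover counting error only. The same replicate numbers in the low and control groups did not mark pairs of oysters in the data, and the samples were treated as independent. Across 90 pairs of libraries within groups, 0 were identical; the lowest chi-square per degree of freedom was 4.77 and the median 17.5. The labels describe separate oysters, so p-values measure the spread between individual animals of 1 rearing, not between repeated rearings or exposures.

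Groups were the 6 combinations of population and salinity in the sample titles, each with 6 libraries. For 2 Oyster Point libraries (low replicate 6 and control replicate 6) a population characteristic in the labels reads Marshall; the titles were followed, and a fit without both was an alternative. All 36 libraries entered 1 fit in edgeR 4.0.16 (R 4.3.3), with TMM factors, 6 group coefficients and the sequencing lane as a covariate. Contigs were kept by filterByExpr on the groups, dispersions were estimated with estimateDisp, and quasi-likelihood tests used glmQLFit with robust moderation. This filter left 41972 contigs holding 99.73% of counts, and the common biological coefficient of variation was 66%. The comparisons were low minus control salinity, averaged over the populations and in each population; the differences of those effects between populations (the interaction) jointly and by pair; any population difference averaged over both salinities; and the 3 population pairs at control salinity. Adjusted p-values are Benjamini-Hochberg within a comparison, with a threshold of 0.05. Levels are CPM with TMM-scaled library sizes, given as mean ± SD, and fold changes are log2 ± SE from the fit. Principal components used log2 CPM (prior count 3) of contigs with a mean log2 CPM of at least 3.

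Gene lists, comparisons, tests and the first set of other settings were fixed before the data were examined. Of the fixed lists, 20 had at least 5 members tested; a list of algal or dietary markers and a list of mitochondrial genes matched 0 contigs. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with the same contigs and model, and adjusted over the lists of a family of comparisons. camera with an estimated correlation and fry stood beside it. fry asks whether the members move 1 way on balance, and does not compare them with other contigs. Counts of members past the threshold came from edgeR, over all contigs and adjusted over the list alone. A further 9 lists (transcription factors, cadherins, protein kinases, ion channels, SLC6 and SLC1 transporters with a corrected signature, RNA helicases, histones, tubulins and kinesins, and retroelements) were added later. The first 8 of these were written after the assembly was read and before expression was tested, and the retroelement list after fold changes had been seen. Further motifs for the families that the text names were chosen and trimmed after fold changes had been seen, and serve as a check on family membership.

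Contigs are named in the text by a fixed rule. From each list it took up to 4 members with the smallest adjusted p among those past 0.05 and with a mean of at least 1 CPM, at most 30 per comparison. At most 2 contigs that rose most and 2 that fell most on the log2 scale could be named by number. A limit was added after the data were seen: families whose motif hit reversed proteins in over 20% of its hits were not named, with 1 exception. The HSP70 family, searched with 2 motifs, had 25 hits and 6 in reversed proteins, which is over the limit. It was named because the hits of 1 motif had entered its count again. Where a contig outside the rule is named, the text says that it was chosen after its values were seen.

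Settings fixed at the outset were median-of-ratios size factors, DESeq2 1.42.0, no filter beyond 1 count, a filter of 1 CPM in 6 libraries, no lane term, a block on the replicate number, a fit without the 2 libraries with conflicting labels, a minimum change of 2-fold, and each lane alone. For lists they were the other set tests and a minimum of 100 residues. Settings added after seeing the data were fits without the 14 libraries under 2 M counts, without each of 3 single libraries, with every library thinned to 321267 counts, with list members limited to those holding a further motif, and the 3 population pairs at low salinity. Other splits of the samples (80 that permuted the salinity labels within each population and 70 that permuted the population labels within each salinity, the real split included and drawn at random because far more exist) were fitted in the same way. Population differences at low and control salinity were also compared in 10 random draws of 18 libraries without lane 4 and in 10 from all lanes, with 4, 2 and 3 libraries per salinity in Loch Lomond, Oyster Point and Marshall. List medians were compared with 10000 random lists matched on contig length or GC content and on expression.

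The fit was tested on simulated data with the same group sizes and depths, with 200 of 39694 contigs changed for the mean salinity effect. It recovered 47 of 66 contigs changed 4-fold, 5 of 67 changed 2-fold and 0 of 67 changed 1.5-fold; of its 55 calls, 3 had no simulated change. DESeq2 made 81 calls in the same data, of which 15 had no simulated change. The simulated counts were drawn with dispersions estimated by edgeR and without a lane effect. Far fewer contigs were changed than were called in the real data, so these shares need not hold there. In the other comparisons, which held no simulated difference between populations, at most 1 contig was called. A simulated list of 30 contigs with 15 raised members had an adjusted camera p of 4.84e-12, and 0 of 20 random lists passed 0.05. Sequences were read with Python 3.11.15 and Biopython 1.88, tables with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.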

Results

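Olympia oysters (Ostrea lurida, the oyster native to the Pacific coast of North America) from 3 populations were held at low or control salinity, and the transcripts of whole adults were counted by RNA sequencing. Loch Lomond and Oyster Point lie in San Francisco Bay and Marshall lies in Tomales Bay; the animals were F2 offspring reared in a common garden. Salinity was lowered over 5 days to 5 ppt (grams of salt per kilogram of water) and held there for 4 days. Controls stayed at full salinity (33 ppt in the sample titles and 34 ppt in the protocol), and all were kept at 12 to 13 °C. Each of the 6 combinations of population and salinity had 6 oysters, 1 library each. The comparisons address which transcripts change at low salinity, and whether populations differ in that change or before it.

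Depth was uneven between the 3 sequencing lanes. Lane 4, with 3 low and 9 control libraries, gave 0.321 to 0.886 M counts per library (median 0.728; M, mega). Lane 3, with 8 low and 4 control libraries, gave 0.769 to 8.119 M (median 7.479), and lane 5, with 7 low and 5 control libraries, 4.338 to 16.131 M (median 9.674). Median totals were 7.522 M in the Loch Lomond control group and 7.667 in its low group, 0.844 and 8.654 in Oyster Point, and 4.138 and 7.136 in Marshall. Oyster Point had 4 of its 6 control libraries and 0 low libraries in lane 4. Lane was a term of the model throughout. Counts of calls within lanes and the agreement of signs between lanes stand beside the pooled salinity effect, with within-lane changes for a few contigs only.

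Salinity was the main axis of variation. On the first principal component, with 20.8% of the variance of 13401 contigs (assembled transcripts), all 18 low-salinity libraries lay above all 18 control libraries, with a lowest low value of -6.42 and a highest control value of -6.94. The next components held 10.8% and 8.1%. Loch Lomond low replicate 3, the shallowest library, lay apart at 104.89 on the first component and -131.66 on the next, and some shallow Marshall libraries lay low on the latter (low replicate 4 at -69.81, control replicate 2 at -75.98).

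**Figure D1:**
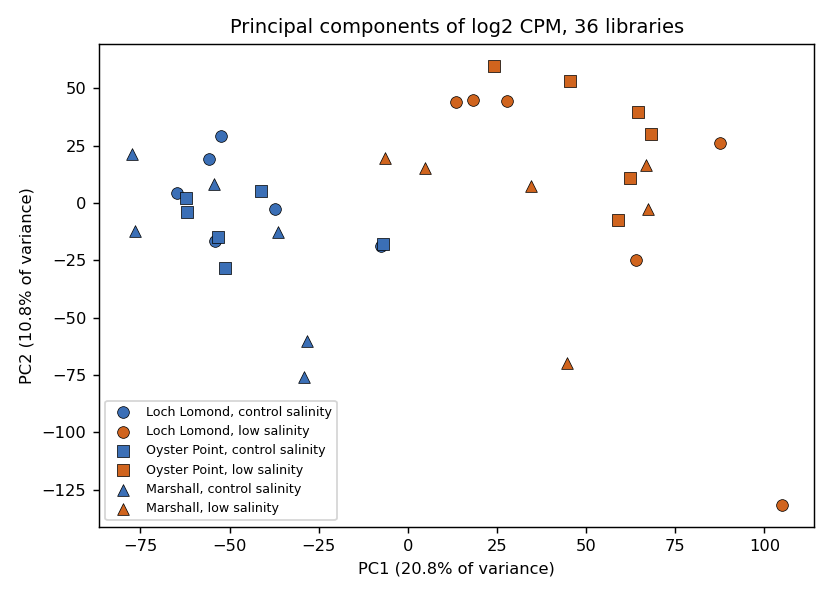
First (horizontal, 20.8% of variance) and next (vertical, 10.8%) principal components of log2 CPM in 36 libraries, 1 point each; colour gives salinity and shape gives population. All 18 low-salinity libraries lie to the right of all 18 control libraries, from -6.42 upward against -6.94 at most, and Loch Lomond low replicate 3 lies apart at the lower right.

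In oysters at 5 ppt, 9 of 17 HSP70-family contigs rose and 1 fell, 9 of 29 contigs with a BIR domain rose and 2 fell, and 3 of 12 myosin contigs rose (n = 18 low and 18 control libraries). Of 6 MCM helicase contigs 5 fell, of 10 aquaporin contigs 4 and of 10 carbonic anhydrase contigs 2. A 650-residue HSP70-family contig, which encodes a chaperone that refolds damaged proteins, rose from 10.58 ± 3.709 to 752.3 ± 394.3 CPM (mean ± SD). Its log2 change was 6.02 ± 0.23 (SE). A 371-residue contig with the BIR and RING domains of inhibitor of apoptosis proteins, which block caspases, rose from 5.87 ± 2.935 to 896.7 ± 633.8 CPM (log2 7.17 ± 0.31). A 733-residue MCM helicase contig, part of the complex that unwinds DNA for replication, fell from 54.39 ± 17.7 to 16.6 ± 7.967 CPM (log2 -1.80 ± 0.22). A 283-residue carbonic anhydrase contig, whose family interconverts carbon dioxide and bicarbonate in acid-base balance and shell formation, fell from 80.33 ± 17.26 to 26.5 ± 15.07 CPM (log2 -1.83 ± 0.18). Averaged over populations, edgeR called 7702 of 41972 contigs at an adjusted p under 0.05, 3771 higher and 3931 lower at low salinity, of which 5525 changed at least 2-fold.

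Chaperones had 13 members that rose and 7 that fell among 55 tested (16 and 9 adjusted over the list alone). The list rose against other contigs (camera adjusted p = 0.000754, median log2 change 0.13, mean 0.69). With an estimated correlation that call was lost (adjusted p = 0.0682 with an estimated correlation), and 9.64% of random lists matched on contig length had a median as high. Within the list, 9 of 17 HSP70-family contigs rose and 1 fell, and 4 of 30 contigs of the DnaJ family, the cochaperones of HSP70, rose and 4 fell. Reversed proteins gave 14 chance hits for the 58 contigs of the list, so some members may lie outside these families. Of the 17 HSP70-family contigs 12 held a further motif, and 7 of those rose and 1 fell. A 549-residue HSP70-family contig rose from 4.307 ± 2.122 to 645.4 ± 295.5 CPM (log2 7.03 ± 0.29, edgeR adjusted p = 3.5e-21), and further 650-residue contigs rose by 6.77 ± 0.33 and 5.61 ± 0.23. In each of these 4 HSP70-family contigs all 18 low libraries lay above all 18 control libraries. Reads may be shared among near-identical HSP70 paralogs, so the split between contigs is uncertain. Abundant HSP70-family transcripts did not all rise: a 431-residue contig, chosen after its values were seen, fell by 0.75 ± 0.15.

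Apoptosis control rose as a list, with 10 members higher and 3 lower of 38 (10 and 3 adjusted over the list alone). Its adjusted camera p was 0.00517 (adjusted p = 0.208 with an estimated correlation). Among 29 contigs with a BIR domain, 9 rose and 2 fell, while of 9 caspase contigs, which encode the proteases of cell death, 1 rose and 1 fell. A 459-residue contig with BIR and RING domains rose from 5.502 ± 3.724 to 107 ± 97.91 CPM (log2 3.87 ± 0.33, edgeR adjusted p = 2.55e-11), with all 18 low libraries above all controls. A 796-residue contig rose by 2.83 ± 0.45 on the log2 scale, with 10 of 18 low libraries above all controls, and a 388-residue contig by 1.25 ± 0.23. The call of the 388-residue contig was lost in lane 4 alone (log2 1.55) and in lane 5 alone (log2 0.62).

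Muscle and actin rose as a list with 6 members higher and 1 lower of 21 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00517). With the correlation estimated, the list missed the threshold (adjusted p = 0.0784 with an estimated correlation). The 3 myosin contigs that rose, of 12, hold the motor signature and the light-chain-binding motifs that muscle and non-muscle myosins share, so they do not mark muscle alone. Those of 912 and 1592 residues rose by 3.99 ± 0.37 (11.39 ± 5.076 to 185.2 ± 174.7 CPM) and 3.12 ± 0.32 (38.17 ± 14.86 to 338.3 ± 307.7 CPM), with all 18 low libraries above all controls in both. The 1523-residue contig rose by 3.47 ± 0.48, and a 248-residue actin-family contig, the filament on which myosins move, by 2.41 ± 0.50.

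Ribosomal proteins rose as a list by small amounts, with 5 members higher and 0 lower of 16 (7 and 1 adjusted over the list alone). The median log2 change was 0.44 (camera adjusted p = 0.00252; adjusted p = 0.455 with an estimated correlation). Short contigs rose more often than long ones across the assembly, and 22% of random lists of the same contig lengths had a median as high. In contrast, the eEF2-like elongation factor contig of 860 residues, which moves the ribosome along messenger RNA, fell from 4958 ± 1274 to 2653 ± 1125 CPM (log2 -1.10 ± 0.14, edgeR adjusted p = 1.17e-07). Contigs of the same family with 108 and 214 residues fell by 1.06 ± 0.16 and 0.38 ± 0.13. The latter call was lost without a lane term (log2 -0.28) and without the 14 libraries under 2 M counts (log2 -0.22). A 78-residue fragment rose by 5.35 ± 0.34. Only 1 contig of this family held a further motif, and it fell. The fragment lacked that motif, as did all but 1 of the contigs that fell. The translation factor list had 1 member higher and 3 lower of 10 (1 and 3 adjusted over the list alone; camera adjusted p = 0.664), with a mean of 0.17 while the test pointed down.

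Cell division fell, with 1 member higher and 7 lower of 13 (1 and 7 adjusted over the list alone). The median log2 change was -0.95 (camera adjusted p = 0.00252; adjusted p = 0.224 with an estimated correlation). Of 6 MCM helicase contigs 5 fell, and of 6 cyclin contigs, regulators of the cell cycle, 2 fell. Both named MCM contigs had 733 residues; the one given above had 15 of 18 low libraries below all controls, and the other fell by 1.74 ± 0.27. The single member that rose was a histone H3 contig.

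Cilia and flagella fell, with 0 members higher and 9 lower of 31 (0 and 12 adjusted over the list alone). Its median log2 change was -0.75 (camera adjusted p = 0.00111; adjusted p = 0.335 with an estimated correlation). Dynein heavy chains, the motors of cilia and of transport along microtubules, made up 8 of those 9, from 22 tested, and a beta-tubulin contig was the other. The 4 tektin contigs, which encode filament proteins of the cilium, had a mean log2 change of -0.26 ± 0.11 (SE across contigs, not oysters), against -0.73 ± 0.14 for the 22 dyneins. Dynein contigs of 1671 and 2355 residues, chosen after their values were seen, fell by 1.87 ± 0.36 and 1.26 ± 0.28. Without the 14 libraries under 2 M counts the list just missed the threshold (adjusted p = 0.0532).

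Ion pumps and osmolyte transport fell, with 0 members higher and 11 lower of 37 (0 and 12 adjusted over the list alone). The median log2 change of the list was -0.43 (camera adjusted p = 0.00553; adjusted p = 0.335 with an estimated correlation). Those that fell were 4 of 10 aquaporins, which are water channels, and 2 of 10 carbonic anhydrases. Also lower were 2 of 7 Na+/K+-ATPases, the pumps that set the sodium gradient, and 3 of 7 SLC5 sodium-coupled transporters. Aquaporin-family contigs of 290 and 310 residues fell by 1.97 ± 0.34 (10.54 ± 5.346 to 3.148 ± 3.113 CPM) and 1.62 ± 0.29 (19.47 ± 6.725 to 8.023 ± 5.809 CPM). Of 18 low libraries 6 and 12 lay below all controls. The mean low level of the 290-residue contig was under the floor of 3 counts in every lane 4 library. Its call was lost in lanes 3, 4 and 5 alone (log2 -2.07, -0.74 and -2). Na+/K+-ATPase contigs of 1044 and 1046 residues, chosen after their values were seen, fell by 0.85 ± 0.25 and 0.80 ± 0.24. The 756-residue carbonic anhydrase contig fell by 1.15 ± 0.33, a call lost without the libraries under 2 M counts (log2 -0.69). It was also lost in lanes 3, 4 and 5 alone (log2 -0.32, -2.07 and -1.17).

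**Figure D2:**
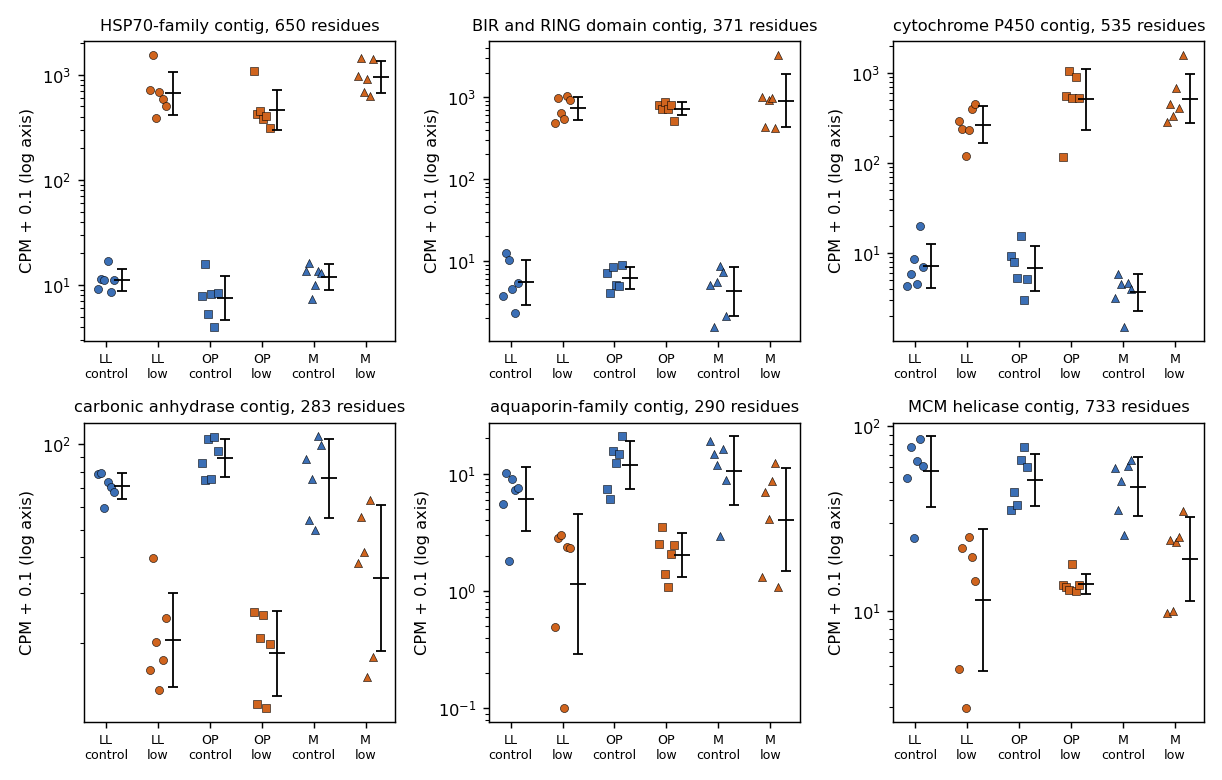
Normalised level (CPM + 0.1, log axis) of 6 named contigs in each library, by population (LL, Loch Lomond; OP, Oyster Point; M, Marshall) and salinity; black marks are means ± SD on the log scale, n = 6. In the HSP70-family, BIR and RING domain and cytochrome P450 panels all 18 low-salinity libraries lie above all 18 controls, and in the carbonic anhydrase panel 16 of 18 lie below all controls.

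Cytochrome P450 enzymes, which oxidise lipids and foreign compounds, went both ways: 13 rose and 9 fell of 78 (14 and 9 adjusted over the list alone; camera adjusted p = 0.532). A 535-residue contig rose from 6.619 ± 4.547 to 506.8 ± 361 CPM (log2 6.20 ± 0.30, edgeR adjusted p = 9.18e-19). A 517-residue contig rose from 8.203 ± 3.606 to 53.83 ± 26.04 CPM (log2 2.50 ± 0.23). In both, all 18 low libraries lay above all controls. A 530-residue contig fell from 89.98 ± 24.83 to 33.9 ± 20.42 CPM (log2 -1.75 ± 0.14), with 12 low libraries below all controls.

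Amino acid and osmolyte metabolism, which supplies the free amino acids that marine molluscs use as osmolytes, had 5 members higher and 12 lower of 63 (7 and 14 adjusted over the list alone; camera adjusted p = 0.209). Membership is uncertain: 11 of the 12 lower members matched an aldehyde dehydrogenase signature, which had 46 hits and also 29 in reversed proteins. A 383-residue glutamine synthetase contig fell from 65.79 ± 18.68 to 26.59 ± 10.75 CPM (log2 -1.42 ± 0.19). A 547-residue glutamate dehydrogenase contig, which links glutamate to energy metabolism, rose from 67.96 ± 18.64 to 139 ± 46.37 CPM (log2 0.99 ± 0.18). Contigs of 1598 and 978 residues with the glutamine synthetase signature rose by 3.66 ± 0.22 and 3.10 ± 0.34, but lacked a further motif of that enzyme and resembled polyproteins of retroelements.

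The other fixed lists did not pass 0.05 with camera, whose adjusted p follows each count, although members of each changed. Shell, mantle and extracellular matrix had 22 members higher and 36 lower of 208 (28 and 39 adjusted over the list alone; adjusted p = 0.13). EF-hand calcium-binding proteins had 35 and 38 of 339 (35 and 39 adjusted over the list alone; adjusted p = 0.708). G protein-coupled receptors had 16 and 7 of 113 (16 and 7 adjusted over the list alone; adjusted p = 0.0925). For other membrane transport it was 18 and 19 of 130 (19 and 21 adjusted over the list alone; adjusted p = 0.752). Innate immune recognition had 5 and 9 of 101 (5 and 9 adjusted over the list alone; adjusted p = 0.752). Digestive and lysosomal hydrolases had 4 and 6 of 94 (2 and 6 adjusted over the list alone; adjusted p = 0.664). Glycolysis and energy metabolism had 2 and 9 of 50 (2 and 11 adjusted over the list alone; adjusted p = 0.285). Antioxidant and metal binding had 5 and 1 of 34 (5 and 1 adjusted over the list alone; adjusted p = 0.3). Nuclear receptors had 3 and 4 of 34 (3 and 4 adjusted over the list alone; adjusted p = 0.586). Ubiquitin and proteasome had 3 and 3 of 29 (5 and 3 adjusted over the list alone; adjusted p = 0.319). Reversed proteins gave 72 chance hits for the 217 contigs of the shell list, 34 for the 52 of glycolysis, 31 for the 118 of G protein-coupled receptors, 33 for the 135 of other transport and 27 for the 105 of hydrolases. For EF-hand proteins it was 49 for 346, for immune recognition 19 for 104 and for antioxidants 5 for 37, so these counts include contigs outside the named families. Of the 36 lower shell members 15 matched the collagen triple helix, with 36 hits in either direction of the protein. The lists of algal or dietary markers and mitochondrial genes matched 0 contigs, so neither was tested. Of the 20 lists tested, 7 passed with the preset correlation and 0 with an estimated one, while fry called 10.

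**Figure D3:**
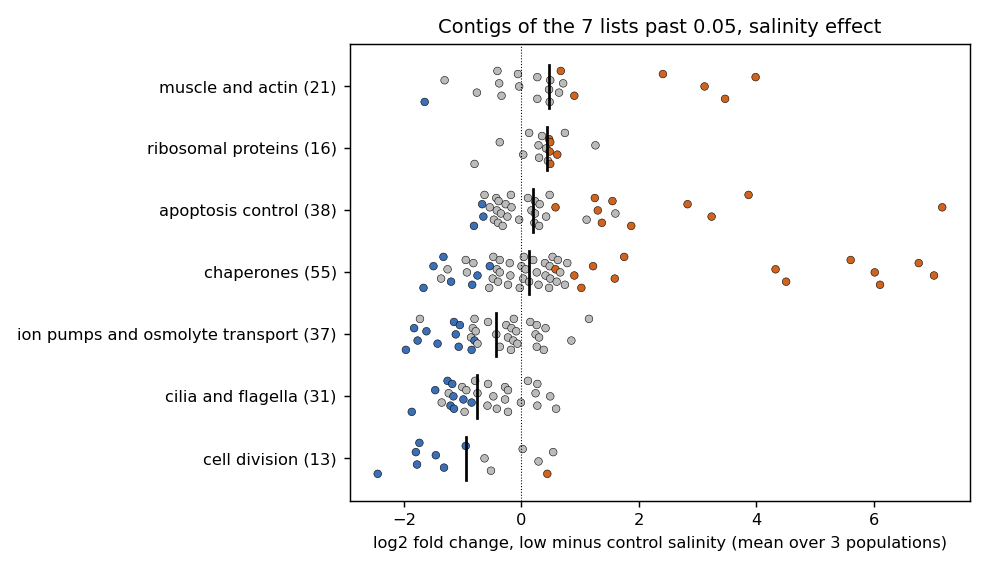
Log2 change at low salinity (horizontal, mean over 3 populations) of every tested contig of the 7 lists past 0.05, 1 point each, with the number of contigs in brackets; orange and blue points rose and fell in edgeR, grey points did not pass, and black bars are medians. Chaperone and apoptosis control contigs form a tail up to 7.17, and the medians of cell division and cilia and flagella lie at -0.95 and -0.75.

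The contig that rose most had an open reading frame with no listed signature: oystercontig_25372 was at 0 counts in 15 of 18 control libraries and at 47.43 ± 56.41 CPM at low salinity, with 16 low libraries above all controls. Next was oystercontig_46256, which rose from 0.3262 ± 0.4643 to 58.41 ± 21.93 CPM (log2 7.79 ± 0.34), with all 18 low libraries above all controls. Among those that fell most, oystercontig_32742 went from 14.1 ± 24.36 to 0.3214 ± 0.3883 CPM (log2 -6.03 ± 0.75). Control levels of this contig ran from 0 to 92.4 CPM; 0 low libraries lay below all controls and all 18 below the control median.

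Within single lanes the salinity effect was called for 639 contigs in lane 3, 617 in lane 4 and 846 in lane 5, and contigs called from the other lanes and tested in the one left out had the same sign in 92.3% (4624 of 5011), 90.6% (2858 of 3153) and 96.2% (3461 of 3599) of cases. Without the 14 libraries under 2 M counts the count was 4832, and with every library thinned to 321267 counts it was 2957 of 8137 tested.

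Single HSP70-family, BIR domain and cytochrome P450 contigs rose in each of the 3 populations (n = 6 low and 6 control oysters in each). Of 17 HSP70-family contigs 6 rose and 1 fell in Loch Lomond, 5 and 1 in Oyster Point, and 7 and 0 in Marshall. Of 29 BIR domain contigs it was 8 and 2, 3 and 0, and 3 and 0, and of 78 cytochrome P450 contigs 10 and 3, 3 and 5, and 3 and 0. The 650-residue HSP70-family contig rose by 5.99 ± 0.38 on the log2 scale in Loch Lomond, 5.82 ± 0.40 in Oyster Point and 6.25 ± 0.39 in Marshall. The 371-residue contig with BIR and RING domains rose by 6.91 ± 0.51, 6.73 ± 0.53 and 7.87 ± 0.55, in the same order. The 535-residue cytochrome P450 contig rose by 5.14 ± 0.48, 6.15 ± 0.53 and 7.31 ± 0.54. edgeR called 2538 contigs in Loch Lomond (1399 higher and 1139 lower), 2336 in Oyster Point (1090 and 1246) and 1305 in Marshall (1040 and 265).

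In Loch Lomond oysters, chaperones rose as a list, with 9 members higher and 2 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.00558; adjusted p = 0.276 with an estimated correlation). Apoptosis control rose with 8 and 2 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0406; adjusted p = 0.545 with an estimated correlation). That call also missed the threshold with a block on the replicate number and with fry. BIR domain contigs of 459 and 304 residues rose by 4.35 ± 0.54 and 4.59 ± 1.00, while one of 623 residues fell by 1.18 ± 0.26. Cell division fell with 0 and 6 (0 and 7 adjusted over the list alone; camera adjusted p = 0.000849; adjusted p = 0.279 with an estimated correlation), with 4 of 6 MCM helicases lower. Ion pumps and osmolyte transport fell with 0 and 4 (0 and 8 adjusted over the list alone; camera adjusted p = 0.0236; adjusted p = 0.699 with an estimated correlation). Catalase contigs, which break down hydrogen peroxide, went both ways, with a 290-residue contig lower by 1.92 ± 0.27 and a 214-residue contig higher by 1.97 ± 0.42. The eEF2-like contig fell by 1.57 ± 0.22, glutamine synthetase by 1.72 ± 0.30 and the 530-residue cytochrome P450 by 2.22 ± 0.24. A 156-residue EF-hand contig rose by 5.86 ± 0.81, and the 912-residue myosin by 3.94 ± 0.61. Without the 14 libraries under 2 M counts the calls of apoptosis control (adjusted p = 0.216) and ion pumps and osmolyte transport (adjusted p = 0.156) were lost, as were those of 6 of 34 named contigs, among them the 623-residue BIR domain contig (log2 -1.02).

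In Oyster Point oysters, chaperones passed with 8 members higher and 4 lower (9 and 7 adjusted over the list alone; camera adjusted p = 0.0292; adjusted p = 0.384 with an estimated correlation). The mean change of the list was 0.39 and the median -0.03. An 83-residue DnaJ contig rose by 6.51 ± 0.59. Apoptosis control rose with 3 and 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00363; adjusted p = 0.276 with an estimated correlation). Cilia and flagella fell with 0 and 6 (0 and 6 adjusted over the list alone; camera adjusted p = 0.00363; adjusted p = 0.725 with an estimated correlation), 5 of them dynein heavy chains. Ribosomal proteins passed with 0 and 0 members called (0 and 0 adjusted over the list alone; camera adjusted p = 0.0326; adjusted p = 0.777 with an estimated correlation). The 283-residue carbonic anhydrase fell by 2.57 ± 0.33, aquaporins of 290 and 310 residues by 2.75 ± 0.62 and 2.12 ± 0.52, and glutamine synthetase by 1.73 ± 0.33. ABC transporter contigs, which export compounds at the cost of ATP, went both ways, with a 1315-residue contig lower by 3.06 ± 0.52 and a 1215-residue contig higher by 1.90 ± 0.42. Without the 14 libraries under 2 M counts all 4 list calls were lost, with adjusted p = 0.0784 for chaperones, 0.0526 for apoptosis control, 0.488 for cilia and flagella and 0.389 for ribosomal proteins. Of 34 named contigs 18 also lost their call there, among them the 290-residue and 310-residue aquaporins (log2 -2.69 and -1.56), glutamine synthetase (-1.55) and the 1215-residue ABC transporter (2.03). The chaperone and ribosomal calls were also lost without a lane term (adjusted p = 0.0817 and 0.0508).

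In Marshall oysters, chaperones rose with 10 members higher and 0 lower (12 and 1 adjusted over the list alone). This call also held with an estimated correlation (camera adjusted p = 1.6e-07; adjusted p = 0.0074 with an estimated correlation). Of 17 HSP70-family contigs 7 were higher. Muscle and actin rose with 3 and 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00558; adjusted p = 0.168 with an estimated correlation). The 3 were myosin contigs, with the one of 912 residues at 4.43 ± 0.64. Ribosomal proteins rose as a list (camera adjusted p = 0.00378; adjusted p = 0.759 with an estimated correlation). Cilia and flagella fell (camera adjusted p = 0.0292; adjusted p = 0.759 with an estimated correlation). Neither list had a member called, with 0 also adjusted over the list alone, and neither passed with fry. The 796-residue BIR domain contig rose by 5.13 ± 0.78, and tyrosinase-family contigs of 699 and 726 residues, a family of shell formation and pigment, rose by 4.13 ± 0.82 and 3.48 ± 0.80. A 1287-residue chitinase-family contig fell by 2.83 ± 0.63 and a 477-residue nuclear receptor rose by 1.25 ± 0.25. The 283-residue carbonic anhydrase fell by 1.20 ± 0.30. Without Marshall low replicate 6, 10 of 34 named contigs lost their call, among them this one (log2 -1.02) and the 1523-residue myosin, one of the 3 (2.86). In the fit without the 14 libraries under 2 M counts 16 did, among them both of these (-1.18 and 3.29) and the nuclear receptor (1.12). The call of the 726-residue tyrosinase was lost without a lane term (3.09).

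Many contigs responded in more than 1 population. In both Loch Lomond and Oyster Point 655 contigs were called higher and 408 lower, against 36.3 and 33.8 expected from independent calls. That expectation takes every tested contig as equally likely to be called, whatever its level or spread, so it does not give the overlap due to chance. The counts were 448 and 93 in Loch Lomond and Marshall (34.7 and 7.2 expected), and 426 and 114 in Oyster Point and Marshall (27 and 7.9 expected). In all 3 populations 341 contigs were called higher and 72 lower. Contigs called with opposite signs numbered 0, 3 and 0 in these pairs. Across contigs, which are not independent replicates, log2 changes correlated with r of 0.52, 0.40 and 0.44. The counts per population depended on depth and on single libraries: without the 14 libraries under 2 M counts they were 1133, 514 and 377. Without the 2 libraries with conflicting labels Oyster Point had 1383, and without Marshall low replicate 6 Marshall had 658. DESeq2 called 4367, 4341 and 2531.

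No contig of a listed family was called as changing differently between populations in edgeR. The joint test of the interaction in edgeR called 1 contig, with a 190-residue open reading frame and no listed signature. It rose from 4.87 ± 3.334 to 231.8 ± 284.3 CPM in Marshall (n = 6 each). The change was from 7.363 to 16.53 CPM in Loch Lomond and from 6.866 to 14.09 CPM in Oyster Point. The log2 difference of its salinity effects was -4.82 ± 0.77 for Oyster Point minus Marshall and -4.09 ± 0.75 for Loch Lomond minus Marshall (edgeR adjusted p = 0.0131 and 0.0344). The latter call was lost without Marshall low replicate 6 (-4.11) and the former without the 2 libraries with conflicting labels (-4.80), where the joint test called 0 contigs. At an unadjusted p under 0.05 there were 3563 contigs, and DESeq2 called 170. By pair, edgeR called 0 contigs between Loch Lomond and Oyster Point (2474 at an unadjusted p under 0.05, 23 in DESeq2). It called 17 between Loch Lomond and Marshall (13 higher and 4 lower, 181 in DESeq2) and 1 between Oyster Point and Marshall (126 in DESeq2). Without Marshall low replicate 6 the 17 became 0 and the last count 2, without Loch Lomond low replicate 3 the 17 became 8, and without Oyster Point low replicate 1 the joint test and the last pair had 4 each. With a block on the replicate number the 17 also became 0, and without a lane term they became fewer.

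As a list, chaperones had a lower salinity effect in Oyster Point than in Marshall (camera adjusted p = 0.0301; adjusted p = 0.386 with an estimated correlation). No member was called, and 0 were higher and 4 lower adjusted over the list alone. The list's call was lost without the 2 libraries with conflicting labels (adjusted p = 0.0558), without the 14 libraries under 2 M counts (adjusted p = 0.114) and with only members holding a further motif (adjusted p = 0.21). A block on the replicate number also ended it. Cell division differed downward between Loch Lomond and Marshall (camera adjusted p = 0.0449; adjusted p = 0.725 with an estimated correlation). It had 0 members called and 0 adjusted over the list alone, and the call was lost without Marshall low replicate 6 (adjusted p = 0.0928). Translation factors differed downward in the same pair (camera adjusted p = 0.0292; adjusted p = 0.276 with an estimated correlation; 0 members called, 0 higher and 2 lower adjusted over the list alone). No list passed 0.05 between Loch Lomond and Oyster Point. Differences in the count of calls between populations are not tests of a difference.

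At control salinity the named contigs that differed were an EF-hand, a nuclear receptor, a trypsin-like and a tyrosinase contig, each between Loch Lomond and Marshall (n = 6 oysters each). A 1108-residue contig with an EF-hand signature, the calcium-binding loop, lacked a further motif of that family. Its level was 424 ± 166 CPM in Loch Lomond and 99.7 ± 19.1 CPM in Marshall (log2 1.99 ± 0.33, edgeR adjusted p = 0.00232). A 433-residue nuclear receptor contig, of the family of hormone-regulated transcription factors, was at 15.2 ± 5.98 and 1.39 ± 2.04 CPM (log2 3.92 ± 0.91). A 266-residue trypsin-like protease contig, of a family with digestive enzymes, was at 124 ± 63.6 and 21.2 ± 11 CPM (log2 2.27 ± 0.57). A 726-residue tyrosinase-family contig was lower in Loch Lomond, at 1.75 ± 1.41 against 27 ± 26.3 CPM (log2 -4.73 ± 1.14). edgeR called 296 contigs between Loch Lomond and Marshall (187 higher in Loch Lomond and 109 lower). It called 34 between Oyster Point and Marshall (26 and 8) and 10 between Loch Lomond and Oyster Point (1 and 9). DESeq2 called 924, 291 and 156. No fixed list passed 0.05 in any of these pairs (camera; lowest adjusted p = 0.319, for cilia and flagella), and no member of a fixed list was called in the last pairs named. The count of lists that passed, 0, became 6 without the 14 libraries under 2 M counts. The trypsin-like call was lost without Marshall low replicate 6 or Oyster Point low replicate 1 (log2 2.26 in both) and the tyrosinase call without Loch Lomond low replicate 3 (-4.74) or Oyster Point low replicate 1 (-4.66), and both under further settings. Without the 14 libraries under 2 M counts the counts were 33, 9 and 5, and the nuclear receptor, trypsin-like and tyrosinase calls were lost, at log2 values of 5.20, 2.46 and -5.48 with fewer libraries.

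Averaged over both salinities, 3188 contigs differed between populations in a joint edgeR test (1506 without the 14 libraries under 2 M counts). Past the threshold in EF-hand proteins were contigs of 1108 (adjusted p = 2.21e-06), 855 (0.000147), 661 (0.000185) and 726 residues (0.000252). A 1276-residue chitinase-family contig (5.14e-05), the 510-residue and 530-residue cytochrome P450 contigs (0.00134 and 0.00225) and nuclear receptors of 433, 406 and 440 residues (0.00327, 0.00396 and 0.0281) also differed. So did trypsin-like contigs of 266, 766 and 994 residues (0.000938, 0.0145 and 0.0192), a BIR domain contig of 348 residues (0.00565), the eEF2-like contig (0.0106), a 202-residue carbonic anhydrase (0.0107) and ABC transporters of 1315 and 1215 residues (0.0119 and 0.012).

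At low salinity, in comparisons and contigs chosen after their values were seen, Marshall oysters had more cytochrome P450, catalase and DnaJ transcript of single contigs than the other populations (n = 6 each; both pairs share the Marshall libraries). The 530-residue cytochrome P450 contig, which fell with salinity, was at 59.4 ± 13.9 CPM in Marshall, 19.3 ± 4.89 CPM in Loch Lomond and 22.9 ± 4.45 CPM in Oyster Point. Against Marshall the log2 differences were -1.55 ± 0.24 and -1.46 ± 0.24 (edgeR adjusted p = 0.00045 and 0.000497). The 290-residue catalase contig was at 161 ± 51.3, 56.4 ± 27.6 and 67.1 ± 15.7 CPM, and a 558-residue DnaJ contig at 737 ± 356, 156 ± 124 and 157 ± 139 CPM. The 1108-residue EF-hand contig was lowest in Marshall at 61.7 ± 28.6 CPM, against 226 ± 64.6 and 257 ± 106 CPM.

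Between Loch Lomond and Marshall at low salinity edgeR called 1236 contigs (661 higher in Loch Lomond and 575 lower). The 1276-residue chitinase was at 15.7 ± 6.96 against 99.6 ± 27.4 CPM, and the eEF2-like contig at 1760 ± 516 against 3940 ± 754 CPM. Also called were the 796-residue BIR domain contig (log2 -3.48 ± 0.74) and the 266-residue trypsin-like contig (log2 2.34 ± 0.56). Between Oyster Point and Marshall it called 1947 (936 and 1011), with 0 HSP70-family contigs higher and 4 lower of 17. Lower in Oyster Point were a 406-residue nuclear receptor (log2 -2.64 ± 0.47), carbonic anhydrases of 202 and 283 residues (-3.48 ± 0.71 and -1.07 ± 0.29) and the glycolytic enzyme enolase (-1.09 ± 0.25). Between Loch Lomond and Oyster Point it called 144 (79 and 65), including the 202-residue carbonic anhydrase (8.62 ± 9.48 against 0.987 ± 0.939 CPM). No list passed 0.05 in these pairs (camera; chaperones between Oyster Point and Marshall, 0 higher and 8 lower of 55, 2 and 12 adjusted over the list alone, adjusted p = 0.203). Without the 14 libraries under 2 M counts the counts were 422, 1045 and 39, and without the 2 libraries with conflicting labels the last pair had 55. Over the 3 pairs edgeR called 9.79 times as many contigs at low as at control salinity. In 10 draws of 18 libraries without lane 4, with equal numbers of low and control libraries in each population, the median ratio was 1.25.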

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

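Chosen only after the results they measure were seen were the comparisons at low salinity, the fits without single or shallow libraries, and the tests of lane and depth, of scaling, of the 4 technical explanations for population differences at low salinity and of the share of ciliated tissue.

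Between low and control salinity edgeR called 7702 contigs, among them HSP70-family, BIR domain, cytochrome P450 and MCM helicase contigs. If sequencing lane or depth had made these calls, they should not carry over between lanes, but contigs called from a pair of lanes had the same sign in the held-out lane in at least 90.6% of cases (lane 4, 2858 of 3153). A scale error common to the low libraries would shift the log2 changes of all contigs alike, but with the low libraries rescaled by log2 shifts from -2 to 2, in steps of 0.25, at least 7702 of all 41972 tested contigs were called, so no such shift accounts for the calls. Both tests speak to the calls as a set and leave single contigs open, and the labels do not say how oysters were placed in tanks, so an effect of tanks cannot be separated. A response to the salinity of the water is therefore a hypothesis that these tests left standing.

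Populations differed in 3327 calls over 3 pairs at low salinity against 340 at control salinity, a ratio of 9.79 (5.3 in DESeq2), with catalase, DnaJ and cytochrome P450 contigs higher in Marshall. Uneven depth is argued against by a ratio of 11.8 with every library thinned to the same total. Conflicting labels are argued against by a ratio of 7.82 without those 2 libraries. A single unusual library is argued against by a ratio of 7.06 without Marshall low replicate 6. That library had the lowest TMM factor (0.467) and the largest share of counts in its 10 most counted contigs (24.7%). Lane 4 stays open: in 10 draws of 18 libraries without it, with as many low as control libraries in each population, the median ratio was 1.25 (0.475 to 5.62), against 3.37 (0.917 to 36) in draws of the same sizes from all lanes. The ratio was 32 without the 14 libraries under 2 M counts, but there 2 control groups were smaller than their low groups, and the test of the difference itself called 1 contig for the interaction and 0, 17 and 1 for the pairs. That populations diverge under low salinity is a hypothesis that the draws without lane 4 did not support, and a difference in spread between oysters of the groups stays open as well.

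The cilia list fell with a median log2 change of -0.75, mostly in dynein heavy chains. Contig length is argued against, since 0% of 10000 random lists of the same lengths and expression had a median as low, and so is GC content, with 0.02%. A smaller share of 1 ciliated tissue would lower its transcripts alike. The 4 tektin contigs changed by -0.26 ± 0.11 (mean ± SE across contigs) and 22 dynein heavy chains by -0.73 ± 0.14, which is 2.62 standard errors apart. Contigs measured in the same oysters are not independent replicates, so this gap does not measure spread between animals. It cannot decide the question, and a smaller share of such a tissue stays open. Loss of some ciliated cells and not others, and lower expression of axonemal or cytoplasmic dyneins, stay open and could not be tested in whole animals. The call of the list was lost with an estimated correlation (adjusted p = 0.335 with an estimated correlation), so this fall is a hypothesis.

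Chance could be excluded for the salinity counts, where only 1 split of 80, the real one, gave as many contigs. The mean effect had 7702 against at most 8 in the others. By population it was 2538 against 4 in Loch Lomond, 2336 against 22 in Oyster Point and 1305 against 6 in Marshall. For lists at the mean effect, 2 of 80 splits gave 7 or more, the real one included, which is a share under 0.05. The other of these gave 13, more than the real split, so chance is not excluded for these list calls. For the lists by population it could not be excluded, with 4 of 80 giving 15 or more (at most 19). Among 70 splits of the population labels, chance could be excluded for the mean over salinities (3188 against 7). For the pairs at control salinity only the real split gave as many (Loch Lomond minus Marshall 296 against 0, Oyster Point minus Marshall 34 against 0, Loch Lomond minus Oyster Point 10 against 1). At low salinity only the real split gave as many in these pairs, with 1236 against 56, 1947 against 21 and 144 against 59. These splits mixed the labels of all 3 populations, so they test whether any population differed. They do not exclude chance for a single pair. Chance could not be excluded for the interaction (1 contig, 7 of 70 splits, at most 11). Nor could it be for the salinity effect of Oyster Point minus Marshall (1 contig, 6 of 70, at most 2). The same held for the lists that differed in their salinity effect (3, with 25 of 70 splits, at most 8). For the salinity effect of Loch Lomond minus Marshall only the real split gave as many (17 contigs against 1). Where the real count was 0 the splits say nothing on chance, since each of the 70 gives as many: Loch Lomond minus Oyster Point (at most 54 in the others) and lists at control salinity (at most 9). The values 54 and 11 came from 1 split, whose count of 11 against a real 1 may point to a structure of the samples other than population, which was not tested.

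Differences between populations in the salinity effect were called by their own tests. The splits did not exclude chance for the interaction, for Oyster Point minus Marshall or for the lists. For Loch Lomond minus Marshall only the real split of 70 gave as many as 17 contigs, with at most 1 in the others. Those splits mixed the labels of all 3 populations, so they do not test this pair alone. The interaction called 1 contig, Loch Lomond minus Marshall 17 (0 without Marshall low replicate 6 and 8 without Loch Lomond low replicate 3) and Oyster Point minus Marshall 1 (2 without Marshall low replicate 6 and 4 without Oyster Point low replicate 1). With a block on the replicate number each of these counts became 0, and without a lane term the 17 became fewer. By camera, cell division (adjusted p = 0.0449; adjusted p = 0.725 with an estimated correlation) and translation factors (adjusted p = 0.0292; adjusted p = 0.276 with an estimated correlation) differed in Loch Lomond minus Marshall. Chaperones (camera adjusted p = 0.0301; adjusted p = 0.386 with an estimated correlation) differed in Oyster Point minus Marshall.

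Single libraries lay apart from the other 5 of their group in 22 of 231 sets of values, where chance gives about 1 in 20, or 11.6. Of these, 8 were in Oyster Point low replicate 1, given as log2 CPM. Its HSP70 contigs of 650 and 549 residues were at 10.09 and 10.13, and its BIR domain contigs of 459 and 796 residues at 4.31 and 1.12. It had the 535-residue cytochrome P450 at 6.89, the 1523-residue myosin at 2.19, the 248-residue actin at -0.83 and oystercontig_32742 at 0.45. Here and below, a value of -0.83 stands for a count of 0. The libraries with this value were shallow, with 1.289 M counts here and 0.579 and 0.723 M in the control libraries below. Marshall low replicate 4 had a total of 0.463 M counts and a value of -69.81 on the next principal component after the first, and Marshall low replicate 6 had a 733-residue MCM contig at 5.07. Marshall control replicates had the 262-residue cytochrome P450 at -0.83 (replicate 2), glutamate dehydrogenase at 6.74 (replicate 6), a 733-residue MCM contig at 2.94 (replicate 4) and oystercontig_46256 at 0.55 (replicate 3). Loch Lomond control replicates had the 549-residue HSP70 at -0.83 (replicate 4), the 78-residue elongation factor fragment at 3.43 and the 290-residue aquaporin at 1.18 (replicate 3), the 756-residue carbonic anhydrase at 3.76 (replicate 1) and oystercontig_25372 at -0.36 (replicate 5). Oyster Point control replicate 1 had a 650-residue HSP70 contig at 3.78 and Oyster Point low replicate 4 a 733-residue MCM contig at 4.2.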

How the results depend on the processing

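Fits without shallow or single libraries, thinned counts, the further motif for list members and the low-salinity pairs were added after seeing the data. No direction of a named contig turned under the alternatives run for it; thinning gave a value for 114 of 156, and single lanes were fitted for the mean effect only. Of 156 named values, median-of-ratios size factors lost 0 calls, DESeq2 4, no lane term 6 and the replicate block 16. Lanes 3, 4 and 5 alone lost 10 of 33, 12 of 31 and 13 of 33. The fit without the 2 conflicting libraries lost 13, that without Marshall low replicate 6 lost 16 and that without the 14 libraries under 2 M counts lost 59, while thinning lost 8 of 114. Of the values fixed at the outset 91 stayed within 1.5 times the reported count and 27 did not; of the added ones 72 did and 42 did not. Groups kept as few as 2 libraries (Oyster Point control) when the shallow ones were left out, so that fit has fewer samples, and thinning left 8137 contigs tested. Elsewhere the cause was not tested.

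The mean salinity count of 7702 became 4832 without the shallow libraries, 2957 thinned, and 639, 617 and 846 in lanes 3, 4 and 5 alone. DESeq2 made more false calls in simulated data, but these were drawn with dispersions from edgeR and do not decide between the tools. It gave 4367 in Loch Lomond, 4341 in Oyster Point, 2531 in Marshall, 170 for the interaction and 4931 for the population mean. For the differences (Loch Lomond minus Oyster Point, Loch Lomond minus Marshall, Oyster Point minus Marshall) it gave 23, 181 and 126. It gave 156, 924 and 291 for the same pairs at control salinity and 661, 2816 and 3791 at low salinity. Without the 14 shallow libraries the counts were 1133, 514 and 377 by population, 5 for the interaction, and 4 and 3 for the differences of Oyster Point and of Marshall from Loch Lomond. They were 1506 for the population mean, 5, 33 and 9 at control salinity and 39, 422 and 1045 at low salinity. Thinned counts gave 1474, 1186 and 726 by population, 0 for the interaction, 0 for Oyster Point minus Marshall, 807 for the population mean, 3, 66 and 17 at control salinity and 20, 463 and 532 at low salinity.

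With the replicate number as a block, the interaction had 0 contigs, Loch Lomond minus Marshall 0, and Oyster Point minus Marshall 0. In this block fit Loch Lomond minus Marshall had 186 at control salinity and 800 at low salinity. The replicate numbers do not pair the samples. Without the conflicting libraries, Oyster Point had 1383, the interaction 0, Oyster Point minus Marshall 0 and the low-salinity pairs with Oyster Point 55 (Loch Lomond) and 1248 (Marshall). Without a lane term, Loch Lomond minus Marshall had 3 and Oyster Point minus Marshall 2. Median-of-ratios factors gave 2 for the interaction, and so did no count filter (2). Leaving out 1 library at a time (Loch Lomond low replicate 3, Marshall low replicate 6 or Oyster Point low replicate 1) gave 658 to 1318 in Marshall, lowest without Marshall low replicate 6, and 1 to 4 for the interaction. It gave 0 to 1, 0 to 18 and 1 to 4 for the differences, 11 to 14 for Loch Lomond minus Oyster Point at control salinity, and 116 to 208, 922 to 1309 and 1589 to 2178 for the low-salinity pairs.

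For lists, an estimated correlation gave 0 of 20 for the mean effect and 1 by population, chaperones in Marshall. fry gave 10 and 14, and all other settings 6 to 9 for the mean effect. By population the other settings gave 11 to 21. At control salinity the count of 0 became 6 without the shallow libraries and stayed 0 in all other settings run, fry and the estimated correlation among them. The replicate block ended the call of apoptosis control in Loch Lomond (camera adjusted p = 0.0504) and of chaperones in Oyster Point minus Marshall (camera adjusted p = 0.0554). Ribosomal proteins in Oyster Point missed the threshold without the conflicting libraries (camera adjusted p = 0.075). By fry, apoptosis control in Loch Lomond (adjusted p = 0.0509), ribosomal proteins in Oyster Point (adjusted p = 0.336) and, in Marshall, ribosomal proteins (adjusted p = 0.144) and cilia and flagella (adjusted p = 0.151) missed the threshold.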

Other observations

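The bZIP factors and cytoskeletal groups below come from lists written after the assembly was read, and the retroelement list, its test and the further motifs were chosen after fold changes were seen. Named contigs in this part were chosen after their values were seen. Contigs with the bZIP domain, a dimerising DNA-binding domain found in stress-responsive transcription factors, rose in 12 cases and fell in 3 of 32 (n = 18 low and 18 control libraries). A 243-residue bZIP contig rose by 5.60 ± 0.17 on the log2 scale but lacked a further motif of the family. Contigs of 310, 171 and 157 residues rose by 4.25 ± 0.33, 5.55 ± 0.58 and 1.54 ± 0.17 (edgeR adjusted p = 3.83e-12, 2.03e-08 and 9.21e-09). By population 6, 7 and 9 of them rose in Loch Lomond, Oyster Point and Marshall, and 0 fell. Homeobox contigs, a family of developmental regulators, rose in 3 cases and fell in 6 of 62. The transcription factor list as a whole had 15 higher and 9 lower of 94 and missed the threshold (camera adjusted p = 0.0509; adjusted p = 0.21 with an estimated correlation). In Marshall it passed with 9 and 0 (camera adjusted p = 0.000746; adjusted p = 0.0707 with an estimated correlation).

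Tubulins and kinesins, the microtubule tracks and their motors, fell as a list with 1 member higher and 10 lower of 44 (camera adjusted p = 0.0106; adjusted p = 0.21 with an estimated correlation). Kinesin contigs of 915 and 1492 residues fell by 1.69 ± 0.30 and 1.52 ± 0.31, and a 461-residue tubulin by 1.12 ± 0.20. SLC6 and SLC1 transporters, which include carriers of taurine and betaine, had 0 higher and 3 lower of 26 (camera adjusted p = 0.344), with a 611-residue SLC6 contig lower by 1.69 ± 0.26. Protein kinases had 24 higher and 46 lower of 317 (camera adjusted p = 0.367), and cadherins 1 and 9 of 91 (camera adjusted p = 0.117). Ion channels had 0 and 5 of 49 (adjusted p = 0.322), RNA helicases 7 and 5 of 40 (adjusted p = 0.367) and histones 1 and 0 of 5 (adjusted p = 0.413). A 211-residue ferritin contig, which stores iron, rose by 1.03 ± 0.16, and an 83-residue DnaJ contig by 6.11 ± 0.32.

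The direction of change followed contig length across the assembly. With tested contigs in 5 groups of about equal size by length, in the shortest (200 to 627 bp) 801 rose and 381 fell, with a median log2 change of 0.067, and in the longest (2836 to 33424 bp) 669 rose and 1385 fell, with a median of -0.179. Against random lists of the same contig lengths, the share with a median as high was 22% for ribosomal proteins, 9.64% for chaperones, 4.04% for apoptosis control and 0.39% for muscle and actin. The share with a median as low was 0.02% for cell division, 1.03% for ion pumps and osmolyte transport and 3.68% for tubulins and kinesins. Matched on GC content, the shares were 4.37%, 12.8%, 5.18% and 1.14% for the lists that rose and 0.05%, 0.52% and 1.64% for those that fell, in the same order. The cause of the trend with length was not tested.

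A pair of contigs with the glutamine synthetase signature resembled retroelement polyproteins, and a general rise of retroelement transcripts was a possible explanation. The retroelement list, which holds both, had 6 higher and 2 lower of 49 (camera adjusted p = 0.6). Its median log2 change was -0.07 with an SD of 1.07, and 2 members reached 3.10, the smaller rise of the pair. A general rise by about that amount is therefore argued against.

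Loch Lomond oysters might hold contigs that rise at low salinity at a higher level beforehand, and contigs that fall at a lower one. In control oysters the median excess of the raised contigs was -0.008 on the log2 scale (permutation p = 0.9, 2-sided, population labels permuted within lane; 95% of permuted values from -0.119 to 0.127). That of the lowered contigs was -0.023 (permutation p = 0.392, 2-sided; -0.052 to 0.052). Neither test showed such a shift, and neither excludes one. The ranges hold permuted values and are not confidence limits, and the raised and lowered contigs were called with these same control libraries.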
